A study of Mus musculus with 16 samples.

How the data were processed

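RNA was measured in 16 libraries of dendritic cells sorted from mouse spleen. Each library belongs to 1 of 4 subsets, named Dec205, pDC, Esamlo and Esamhi in the labels, and to 1 of 2 genotypes, WT or CKO, with 2 libraries in each of the 8 groups. The series title and design text name Etv6, a transcription factor of the ETS family, as the gene under study. The labels do not say whether the 2 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Per the labels' protocols, sorted cells were taken up in Trizol LS, RNA was purified with the PicoPure kit, and cDNA was made with the SMART-seq v4 Ultra Low Input kit, which amplifies full-length cDNA by PCR without molecular identifiers.

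The values used were the raw counts per gene deposited by the authors, as whole numbers in 1 table of 24116 genes and 16 columns named by the sample titles. Per the submitters' processing notes, the tools named were bcl2fastq, Trimmomatic 0.36 and Bowtie2 2.2.9, with the genome build mm10. The counting tool, its treatment of strand and of reads that match several genes, and the gene annotation are not given in the sources used here. Bowtie2 does not split reads across introns, so if reads were aligned to the genome with it, reads over exon junctions were lost in a share that depends on the gene, alike in both genotypes. The kit does not mark strand, so reads of overlapping genes cannot be told apart. Uncertain for that reason, or because near-identical copies can share reads, are Pydc3 and Pydc4, Cxx1b, Ctla2b, Gm8221 and Apol7c, Ifit1bl1, the Oas1 and Bcl2a1 genes, the H2 genes, Rnaset2b, Ms4a6c, the overlapping pairs Fam217b with Ppp1r3d and Ccl3 with Ccl4, and Itgad with its neighbours Cox6a2 and 4931431B13Rik. The table held no immunoglobulin or T cell receptor constant genes and none of the 15 mitochondrially encoded genes listed, and of 650 entries in the gene lists 29 had no row. Positions were taken from the RefSeq annotation of GRCm38.p6, the assembly that mm10 corresponds to, by Entrez identifier, which placed 24061 of the 24116 genes.

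Totals per library ran from 14434287 to 20709265 counts. The floor used for genes at 0 was 3 counts, which corresponded to 0.143 to 0.228 CPM. Intervals and floors of this kind cover counting error only. Genes were kept by filterByExpr on the 8 groups, which left 13790 tested genes that held at least 99.98% of the counts of each library. Counts were scaled by TMM, with factors from 0.913 to 1.1. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3; estimateDisp and glmQLFit with robust = TRUE), two-sided, with 1 coefficient per group and no covariate, so that all 16 libraries shared 1 estimate of spread per gene with 8 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the tested genes, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken from the F statistic. CPM values were computed from TMM-scaled library sizes and are given as mean ± SD of the 2 libraries of a group. Log2 CPM used a prior count of 2.

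The comparisons were CKO against WT in each subset, their average over the 4 subsets, the joint test of whether the CKO effect differed between subsets (3 degrees of freedom in the numerator), the differences of Dec205 from each other subset, and the differences between subsets in WT. Of the 31 gene lists, 30 had tested genes. They covered identity genes of cDC1, cDC2, ESAM-high cDC2 with Notch targets, ESAM-low cDC2 with monocyte-like genes, and pDC. Lists of function held DC transcription factors and growth factor receptors, type I interferon response, MHC class I presentation and cross-presentation, MHC class II presentation, DC maturation and costimulation, chemokines and cytokines, Toll-like receptor pathway and C-type lectin receptors. Further ones held cell cycle, apoptosis regulators, lysosome, oxidative phosphorylation, glycolysis, cholesterol synthesis, ribosomal proteins, and immediate-early and heat shock genes. The rest were markers of B cells, plasma cells, T cells, NK cells, macrophages, monocytes, neutrophils, and erythroid cells with platelets, and sex-linked genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated for each list. Subset signatures were genes higher in 1 subset than in each of the others by at least 1 on the log2 scale, averaged over both genotypes so that the choice did not favour a genotype. Overlaps of calls were tested with Fisher's exact test in 12 tests.

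Named genes follow a rule. In each comparison of CKO with WT they are the 10 genes with the largest rise and the 10 with the largest fall in log2 fold change among called genes with a mean log2 CPM of at least 3 in the subset and both CKO libraries beyond both WT libraries; gene models without a proper name were counted but not named. For each list they are up to 4 members with the smallest adjusted p, for the joint test the 10 smallest adjusted p at a mean log2 CPM of at least 3, and for WT differences and signatures members of the identity lists. Etv6 is always named. A few further genes, named as chosen after their values were seen, fall outside the rule. Groups, tests, gene lists, the rule and most alternatives were fixed before the data were examined.

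The procedure was tested on simulated data drawn from the real means and library sizes, with 200 genes changed in the CKO libraries of 1 subset. The 200 were drawn from genes above a minimum mean CPM in that subset, so the recovered shares do not cover genes of lower level. For Dec205, over 13520 genes, 57% of the genes changed 2-fold and 92% of those changed 4-fold were recovered, with 4 false calls. For Esamhi, over 13507 genes, the shares were 54% and 94%, with 8 false calls. Each gene had 1 dispersion for all 16 libraries, and 1 simulation was run per subset. These values therefore do not cover the larger spread of the real Dec205 replicates. Alternatives covered the scaling (RLE, upper quartile, library size only), the test (DESeq2 1.42.0, limma-voom, edgeR without robust estimation, glmTreat against a fold of 1.5), the low-count filter, replicate number as a block, fits on the 4 libraries of 1 subset, gene set tests with fry, and each library left out in turn. A limma-voom fit with 1 quality weight per group and a fit on autosomal genes were added after the data had been seen.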

Results

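The RNA of 4 kinds of dendritic cell (DC) from mouse spleen was compared between WT and CKO, with 2 libraries per subset and genotype and 16 in all. In the series, CKO stands for cells made deficient in Etv6, per its design text. Dec205 names a surface receptor of the cross-presenting classical DC (cDC1), pDC the plasmacytoid DC, and Esamlo and Esamhi the ESAM-low and ESAM-high classical DCs of the cDC2 lineage. The libraries held 14434287 to 20709265 counts each. Between 12806 and 15252 genes had at least 1 count. The 10 most abundant genes took 14.5% to 16% of the counts in the Dec205 libraries and 6.6% to 7.22% in the pDC libraries. Replicates of Dec205 lay furthest apart, with a biological coefficient of variation of 20.6% in both genotypes, against 10.6% in Esamhi WT and 10.5% in Esamhi CKO. In a principal component analysis the first component, with 49.7% of the variance, set the pDC libraries (150.6 to 169.3) apart from all others (-64.8 to -39.1), and the second, with 22.1%, set Dec205 apart.

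Etv6 (Entrez 14011), the targeted gene, lies on chromosome 6 from 134035700 to 134270158 (GRCm38) and was detected in every library. In Dec205 it fell from 337 and 375 CPM in the WT libraries to 205 and 219 CPM in the CKO libraries, a log2 fold change of -0.75 (SE 0.1, n = 2 per group, edgeR quasi-likelihood adjusted p = 0.000996). In pDC the WT libraries had 346 and 352 CPM and the CKO libraries 363 and 322 CPM, and the log2 fold change was -0.03 (SE 0.1, adjusted p = 1). The changes of -0.36 (SE 0.1, adjusted p = 0.255) in Esamlo and -0.19 (SE 0.1, adjusted p = 0.812) in Esamhi did not pass the test. The joint test of a difference between subsets gave an adjusted p of 0.0686. A count over the whole gene can stay high when only some exons are deleted, so these values check the genotype labels only weakly.

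A second property of the libraries followed genotype. Xist, the RNA that silences an X chromosome in female cells, was at 0 to 1.44 CPM in the 8 WT libraries and at 114 to 355 CPM in the 8 CKO libraries. Ddx3y, on the Y chromosome, was at 105 to 222 CPM in the WT libraries and at most 1.95 CPM in the CKO libraries, and Kdm5d, Eif2s3y and Uty were likewise seen in WT and at most 1.03 CPM in CKO. Sex and genotype therefore coincided in all 16 libraries, and every comparison of CKO with WT below is also a comparison of these sex-linked patterns. X-linked genes made up 39 of the 935 called genes in Dec205 (4.17%, against 3.27% of the tested genes, Fisher's exact p = 0.126). Autosomal genes made up 892 of the calls in Dec205, 242 in pDC, 69 in Esamlo and 111 in Esamhi.

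The WT libraries show what the subsets expressed before any comparison of genotypes. Of 30 cDC1 identity genes, 29 were higher in Dec205 than in the mean of the other subsets, among them Xcr1, a chemokine receptor of cDC1, at 1250 ± 34 CPM (SD, n = 2) in Dec205 and 14.2 ± 3.39 CPM in Esamhi. Of 30 pDC identity genes, 29 were higher in pDC, among them Siglech, a pDC receptor, at 5550 ± 195 CPM in pDC and 1.38 ± 0.517 CPM in Dec205. Of 27 cDC2 identity genes, 23 were higher in Esamlo and 20 in Esamhi. Esam itself was at 147 ± 5.22 CPM in Esamhi, 32.8 ± 0.497 CPM in Dec205 and 12.6 ± 1.56 CPM in Esamlo, while Lyz2, the lysozyme of myeloid cells, was at 2890 ± 535 CPM in Esamlo and 275 ± 16.4 CPM in Esamhi. Each subset differed from the mean of the others in many genes, from 2347 higher and 1330 lower in Esamlo to 3496 higher and 3678 lower in pDC (edgeR quasi-likelihood test, adjusted p under 0.05).

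The first comparison asked what changed in Dec205 cells, the cross-presenting DCs being the subject of the series title. Cd8a, the CD8 alpha chain carried by lymphoid-organ cDC1, fell 10.6-fold from 740 ± 58.3 to 69.9 ± 1.04 CPM (adjusted p = 4.25e-05), while Plac8 rose 6.12-fold from 324 ± 22.6 to 1980 ± 193 CPM (adjusted p = 1.21e-06). Aoah, an enzyme that inactivates bacterial lipopolysaccharide, went from 0.743 ± 0.192 to 245 ± 27.5 CPM, and Col17a1, a collagen of epithelial anchoring junctions, from 5.62 ± 2.68 to 180 ± 41.7 CPM. Runx2, a transcription factor with a role in pDCs, rose 8.8-fold from 15.2 ± 5.99 to 135 ± 33.8 CPM. In total 474 genes were higher and 461 lower in CKO, of which 309 and 188 by at least 2-fold. Higher genes made up 50.7% of the calls, and 60% when scaled by library size only. All values here come from edgeR's quasi-likelihood test on 2 libraries per group.

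The other named genes that rose in Dec205 were Tgm2, a transglutaminase (18.6-fold), and the interferon-induced Ifit1bl1 (18.2-fold) and Ifi44 (12.6-fold). So did Qpct, a glutaminyl cyclase (11.5-fold), Ctla2b (8.43-fold), the X-linked Cxx1b (7.59-fold) and Gimap4, a lymphocyte GTPase (7.41-fold). Those that fell were the Y-linked Ddx3y, Gp2 (7.69-fold), Proser2 (5.76-fold), the Notch receptor Notch4 (5.75-fold), Tspan9 (5.33-fold), Gclc, a subunit of the enzyme that starts glutathione synthesis (4.65-fold), the cell cycle inhibitor Cdkn2b (4.42-fold), Clu (4.42-fold) and 1 unnamed gene model. With each library of the subset left out in turn, 15 of these 20 genes kept their call, and Gimap4, Proser2, Tspan9, Cdkn2b and Clu lost it in at least 1 fit, with edgeR adjusted p up to 0.0974, 0.154, 0.132, 0.057 and 0.0833. The libraries concerned were CKO replicate 1 or WT replicate 2 for Gimap4, all but CKO replicate 2 for Proser2, CKO replicate 2 or WT replicate 2 for Tspan9, CKO replicate 1 for Cdkn2b, and all but WT replicate 2 for Clu.

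**Figure D1:**
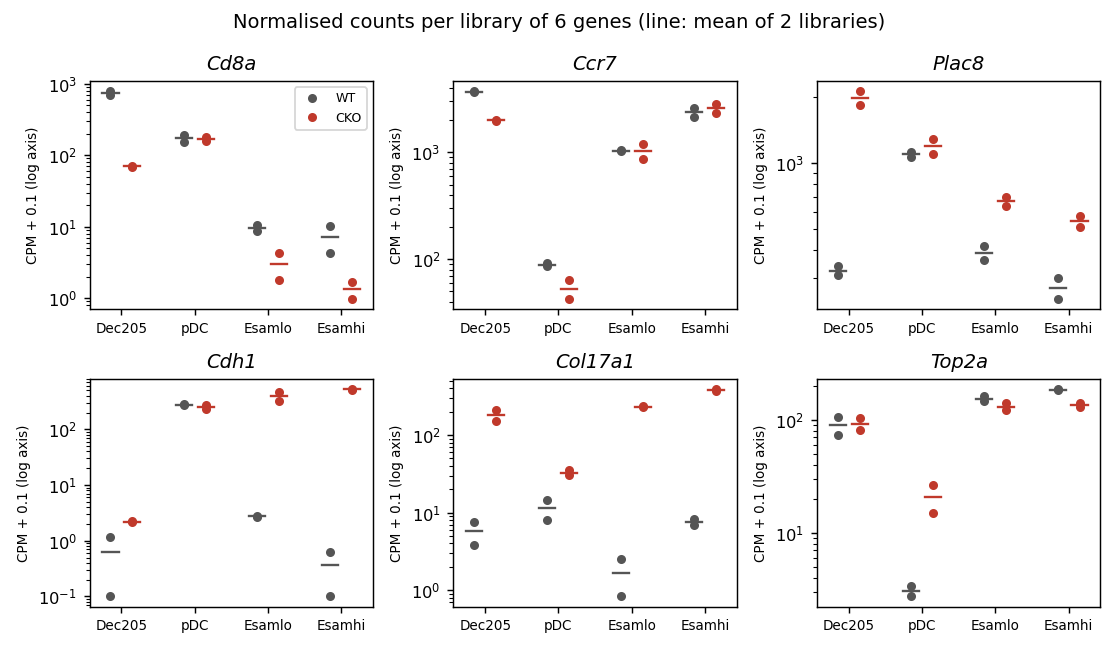
CPM (plus 0.1, log axis) of 6 genes in each of the 16 libraries, by subset on the horizontal axis, with WT in grey, CKO in red and a line at the mean of 2 libraries. Cd8a and Ccr7 were lower and Plac8 higher in Dec205 CKO than in Dec205 WT, Cdh1 was near 0 in Esamhi WT and at 518 CPM in Esamhi CKO, and Top2a was higher in pDC CKO than in pDC WT but below the level of the other subsets.

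The type I interferon response list rose in Dec205. Of its 36 measured genes 15 were higher, 1 lower and 20 not called (20 higher and 2 lower when adjusted over the list alone). The median log2 fold change was 0.60, with a camera adjusted p of 1.28e-16, and of 0.0293 with an estimated correlation. Ifi47, a GTPase, rose 4.25-fold from 28.8 ± 7.26 to 123 ± 5.98 CPM, Oas1a from 1.92 ± 1.47 to 30.2 ± 1.96 CPM, Rtp4 from 0.379 ± 0.537 to 22.7 ± 3.9 CPM, and the apoptosis-related Xaf1 from 8.37 ± 2.61 to 43.6 ± 5.68 CPM. Rsad2, an antiviral enzyme named as the 1 lower member after its value was seen, fell 2.23-fold.

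The DC maturation and costimulation list fell. Of its 25 genes none was higher and 7 were lower (0 and 11 adjusted over the list alone). The median log2 fold change was -0.40, with a camera adjusted p of 3.75e-07, and of 0.138 with an estimated correlation. Ccr7, the receptor that guides mature DCs to lymph nodes, fell 1.85-fold from 3710 ± 31.3 to 2000 ± 35.3 CPM. Relb, an NF-kB subunit, fell from 382 ± 17.6 to 212 ± 10.9 CPM, Traf1 from 644 ± 9.59 to 425 ± 15.4 CPM, and Tmem123 from 2700 ± 32 to 1520 ± 102 CPM.

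The pDC identity list rose in Dec205, with 8 of 30 genes higher, 2 lower and 20 not called (the same counts when adjusted over the list alone) and a camera adjusted p of 0.00205, and of 0.0902 with an estimated correlation. Besides Runx2, the pDC regulator Tcf4 rose from 36.3 ± 8.72 to 75.2 ± 18.5 CPM, and Cox6a2, which lies beside Itgax, went from 0.0718 ± 0.00584 to 6.18 ± 4.89 CPM. Lifr went the other way, from 1.48 ± 0.486 CPM to no count in CKO, at least 17.5-fold lower against a floor of 3 counts over the group. Of the 1084 genes of the pDC signature, 100 were higher and 28 lower in Dec205 CKO (median log2 fold change 0.10, camera adjusted p = 0.00554, and adjusted p = 0.17 with an estimated correlation). The median was 0.02 without CKO replicate 1 and 0.01 without CKO replicate 2. The Dec205 signature of 540 genes had 20 higher and 42 lower (median -0.19, camera adjusted p = 0.0379, and adjusted p = 0.391 with an estimated correlation), which did not pass camera, even without adjustment, when CKO replicate 1 was left out (median -0.13). The cDC1 identity list was not called (camera adjusted p = 0.964), with 1 gene higher (Rnase6, 1.25-fold), 1 lower (Cd8a) and 28 not called. Itgae, the CD103 chain, was at 232 ± 38.1 CPM in WT and 624 ± 135 CPM in CKO (adjusted p = 0.0773).

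Markers of other cells also moved in Dec205. The B cell list rose, with 4 of 15 genes higher, none lower (11 and 0 adjusted over the list alone) and a camera adjusted p of 1.99e-05, and of 0.4 with an estimated correlation. Ms4a1 rose from 51.6 ± 0.81 to 143 ± 3.5 CPM. This rise ran beside that of the pDC list, which shares Spib with the B cell list (34.5 ± 12.1 and 64.4 ± 16.7 CPM). The monocyte list rose with Plac8, Ms4a4c, Ly6c2 and Ccr2 higher and 1 gene of 14 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.00205, and adjusted p = 0.0557 with an estimated correlation). CKO replicate 1 stood apart in both lists: the mean log2 CPM of the monocyte genes was 2.63 and 2.64 in the WT libraries and 3.36 and 2.67 in the CKO libraries, and that of the B cell genes 3.61 and 3.49 in WT and 5.09 and 4.20 in CKO. Both lists kept their call without it. The other 24 lists, sex-linked genes aside, had camera adjusted p from 0.051 to 0.964. Camera tests for a shared direction, so a list that moved both ways is not called. Of 27 cDC2 identity genes 4 were higher and 3 lower (9 and 5 adjusted over the list alone, camera adjusted p = 0.964). Within these 24 lists Il12b, a cytokine subunit, fell 2.5-fold from 1140 ± 8.28 to 455 ± 104 CPM. Esam fell 4.41-fold from 32.8 ± 0.497 to 7.44 ± 0.066 CPM. The size of the Dec205 count depended on the libraries fitted: with only the 4 Dec205 libraries 136 genes were called. That fit changes the estimate of spread and its degrees of freedom together, so their shares were not tested. DESeq2 called 1707 genes and glmTreat against a fold of 1.5 called 257.

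**Figure D2:**
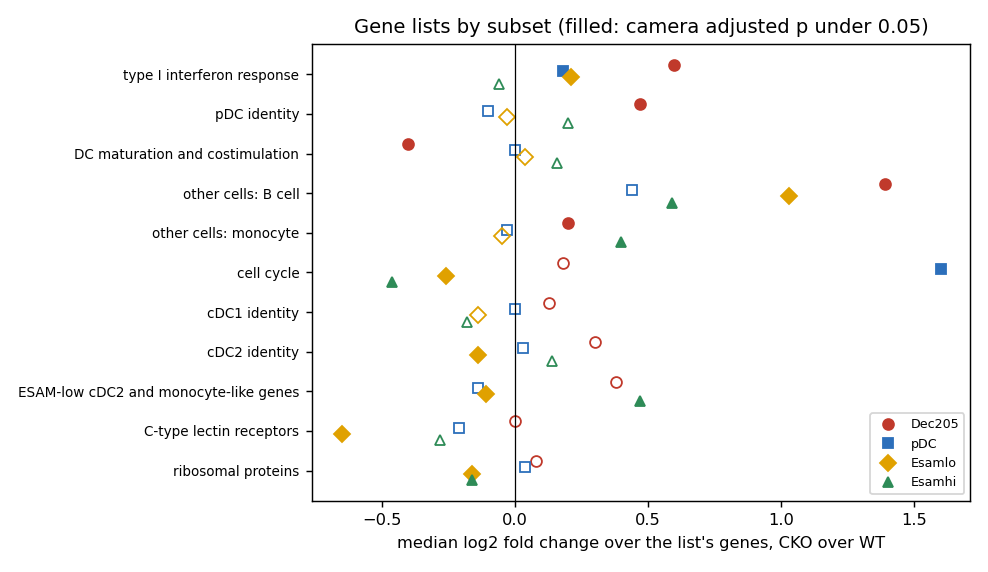
Median log2 fold change (CKO over WT) of 11 gene lists, 1 symbol per subset, filled where the camera adjusted p (preset correlation 0.01) was under 0.05. The interferon list stood at 0.60 in Dec205 and the cell cycle list at 1.60 in pDC, while the maturation list stood at -0.40 in Dec205.

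In pDC, genes of cell division were higher in CKO. Of 24 cell cycle genes 10 were higher and none lower (17 and 0 adjusted over the list alone). The median log2 fold change was 1.60, with a camera adjusted p of 3.7e-30, and of 0.0104 with an estimated correlation. Top2a, a topoisomerase of dividing cells, rose 7.02-fold from 2.95 ± 0.436 to 20.7 ± 8.23 CPM, Kif11 from 1.86 ± 0.692 to 10.6 ± 1.23 CPM, Ccnb2 from 2.51 ± 0.383 to 10.9 ± 1.78 CPM and Cdk1 from 1.32 ± 0.783 to 5.02 ± 0.817 CPM. In total 203 genes were higher and 52 lower (edgeR quasi-likelihood test, 2 libraries per group).

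The interferon list rose in pDC as well, with 6 of 36 genes higher and none lower (12 and 3 adjusted over the list alone, camera adjusted p = 6.33e-05, and adjusted p = 0.268 with an estimated correlation). Oas2 rose 19.8-fold from 1.81 ± 0.746 to 36.1 ± 0.782 CPM and Usp18 1.99-fold from 62.8 ± 0.933 to 125 ± 5.98 CPM. The Toll-like receptor list rose, with Tlr2 (2.43-fold) and Tlr1 higher of 22 genes and none lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.00975, and adjusted p = 0.143 with an estimated correlation). The apoptosis list rose with 3 Bcl2a1 genes higher and Bcl2l11, a pro-apoptotic gene, lower (1.53-fold) of 18 genes (4 and 1 adjusted over the list alone, camera adjusted p = 0.0406, and adjusted p = 0.143 with an estimated correlation), and lost its call without CKO replicate 2 or WT replicate 1 (adjusted p up to 0.342). The pDC identity list had no called gene and a camera adjusted p of 0.346. The 25 lists not called, this one included, ranged from 0.0647 to 0.818.

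Named genes that rose in pDC included Plpp2 (27-fold), Pydc3 (12.3-fold) and Pydc4 (9.96-fold), of an interferon-inducible cluster, the integrin Itgam (6.13-fold), Pros1, protein S of coagulation (6-fold), Plcb4, a phospholipase C (5.57-fold), Rasgef1b (4.21-fold) and Bcl2l14 (4.18-fold), besides Xist and Oas2. Those that fell were smaller in size: Itpripl2 (2.64-fold), Ggta1 (2.36-fold), Fam49a (2.13-fold), Gbp8 (2.07-fold), Rhob (1.99-fold), Serpina3f (1.9-fold), Klf10 (1.86-fold), Adap1 (1.86-fold), Cd244 (1.82-fold) and Plekhg3 (1.79-fold). All 10 that rose kept their call with any 1 library of the subset left out, and of those that fell only Fam49a and Cd244 did. With the spread of the 4 pDC libraries alone 91 genes were called, among them 11 of these 20. Bcl2l14 (edgeR adjusted p = 0.0588) and Fam49a (0.123) were among those not called there. DESeq2 called 549 genes.

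In Esamlo, Cdh1, the adhesion protein E-cadherin, rose 147-fold from 2.67 ± 0.0764 to 393 ± 96.9 CPM (adjusted p = 3.36e-06) and Col17a1 141-fold from 1.59 ± 1.21 to 232 ± 2.72 CPM. Plcb4 rose 18.9-fold, the cotransporter Slc12a7 8.53-fold, Ppp1r3d 8.28-fold, the complement factor Cfb 6.4-fold, Qpct 5.42-fold, Fam217b 4.87-fold and Chst10 4.76-fold. The genes that fell by the rule were Apol7c (2.21-fold), the transcription factor Sox4 (2.05-fold), Plxdc1 (1.77-fold), the cytokine receptor Lifr (1.75-fold), Stard5 (1.58-fold), Rgs18 (1.56-fold) and Tagln2 (1.52-fold). In total 63 genes were higher and 13 lower (edgeR quasi-likelihood test, 2 libraries per group). Leaving out any 1 Esamlo library left 28 to 38 calls, and Ppp1r3d, Cfb, Chst10 and the 7 named falls each lost their call in at least 2 of those fits.

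Of the lists in Esamlo, 5 rose and 7 fell with camera, most with no gene called singly. With an estimated correlation 2 kept their call. The cDC2 identity list fell with 0 of 27 genes called (0 and 5 adjusted over the list alone, median -0.14, camera adjusted p = 0.000454, and adjusted p = 0.0359 with an estimated correlation). Its Mgl2, a lectin, was at 27 ± 1.54 CPM in WT and 6.89 ± 0.405 CPM in CKO (adjusted p = 0.1). The C-type lectin list had 0 of 21 genes called (0 and 4 adjusted over the list alone, median -0.65, camera adjusted p = 0.000178, and adjusted p = 0.0359 with an estimated correlation), with Clec10a at 47.8 ± 2.74 and 18.7 ± 0.841 CPM. The interferon list rose with 2 of 36 genes higher and none lower, among them Ifi47 by 1.89-fold (4 and 0 adjusted over the list alone, camera adjusted p = 0.000225, and adjusted p = 0.235 with an estimated correlation), and lost its call without WT replicate 1 (adjusted p = 0.137).

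The remaining rising lists in Esamlo were MHC class I presentation (0 of 26 genes called, 7 and 0 adjusted over the list alone, camera adjusted p = 0.0017, and adjusted p = 0.0863 with an estimated correlation), apoptosis regulators (0.00411 and 0.064), DC transcription factors and growth factor receptors (0.0285 and 0.136, with Csf2rb2 up 1.82-fold) and B cell markers (2.22e-05 and 0.31). The B cell list lost its call without CKO replicate 1 (adjusted p = 0.145). The remaining falling lists were ribosomal proteins (1.15e-06 and 0.488), oxidative phosphorylation (3.11e-06 and 0.398), cell cycle (0.000688 and 0.31), ESAM-low cDC2 and monocyte-like genes (0.0129 and 0.0863), and chemokines and cytokines (0.0434 and 0.36). Without WT replicate 1 the calls of the apoptosis, cell cycle, transcription factor, ESAM-low and chemokine lists ended. Without CKO replicate 2 that of the transcription factor list ended too, and without CKO replicate 1 that of the chemokine list. Over the fits without 1 library the highest camera adjusted p of these lists was 0.0753, 0.0753, 0.137, 0.0656 and 0.695. The other 17 lists ranged from 0.112 to 0.986.

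In Esamhi, Cdh1 was near the floor in WT, at 0 and 0.519 CPM, and at 527 and 510 CPM in CKO (adjusted p = 4.77e-07). Col17a1 rose 50.8-fold from 7.48 ± 1.01 to 381 ± 15.3 CPM, Slc12a7 27.9-fold, Plcb4 16.3-fold, Ttn 13.4-fold, Cfb 10.7-fold, Hpgd, an enzyme that degrades prostaglandins, 8.99-fold, Fam217b 7.07-fold and the complement receptor C5ar2 6.96-fold. Among the falls were the chemokines Ccl4, from 703 ± 110 to 250 ± 10.2 CPM (2.81-fold), and Ccl3 (2.64-fold), and Cd4, from 280 ± 18.6 to 134 ± 12.2 CPM (2.08-fold). Lag3 (3.03-fold), Zc3h12c (1.9-fold), Hsph1 (1.84-fold), Rilpl2 (1.77-fold) and Adam19 (1.7-fold) fell too. In total 93 genes were higher and 28 lower (edgeR quasi-likelihood test, 2 libraries per group), and with the spread of the 4 Esamhi libraries alone 578 were called. Leaving out any 1 Esamhi library left 44 to 48 calls; of the 20 genes that the rule took, 9 kept theirs in all 4 such fits. Cd4 lost its call in each of them, as did Ttn, Cfb, Lag3, Hsph1 and Adam19, and Ccl3, C5ar2, Zc3h12c and Rilpl2 did in some. The log2 fold change of Cd4 stayed at -1.16 to -0.97 over the alternatives. With the spread of the 4 Esamhi libraries alone all 20 genes kept their call. The same check kept 15 of 20 named genes in Dec205, 11 of 20 in pDC and 13 of 17 in Esamlo.

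Of the lists in Esamhi, 9 rose and 4 fell with camera, and 3 kept their call with an estimated correlation. The ESAM-low and monocyte-like list rose with 0 of 20 genes called (1 and 0 adjusted over the list alone, median 0.47, camera adjusted p = 0.00262, and adjusted p = 0.046 with an estimated correlation), with Lyz2 at 275 ± 16.4 CPM in WT and 735 ± 42.4 CPM in CKO (adjusted p = 0.0616). Its camera call was lost without WT replicate 1 (adjusted p = 0.0672). Along the same line, the Esamlo signature of 61 genes had a median of 0.46 in Esamhi CKO with 2 genes higher and none lower (camera adjusted p = 1.32e-06, and adjusted p = 0.17 with an estimated correlation). This median was 0.25 without WT replicate 1, 0.84 without WT replicate 2 and 0.29 without CKO replicate 1. With the signature chosen from WT replicate 1 and the effect taken without that library it did not pass camera, even without adjustment. The apoptosis list rose with 0 of 18 genes called (4 and 0 adjusted over the list alone, camera adjusted p = 0.00191, and adjusted p = 0.046 with an estimated correlation). The neutrophil list rose with 0 of 14 genes called (4 and 0 adjusted over the list alone, median 1.66, camera adjusted p = 0.000569, and adjusted p = 0.046 with an estimated correlation), at low levels such as S100a8 at 2.28 ± 0.366 and 9.07 ± 0.554 CPM.

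Cell cycle genes fell in Esamhi, with 0 of 24 called singly and every 1 of them below WT in log2 fold change (0 and 1 adjusted over the list alone, median -0.46, camera adjusted p = 5.06e-10, and adjusted p = 0.0677 with an estimated correlation). The list of DC transcription factors and growth factor receptors rose with Irf8, a factor required for cDC1 (1.75-fold, from 79.6 ± 4.97 to 139 ± 18 CPM), Nfil3 (1.72-fold) and Csf2rb2 (2.2-fold) higher of 30 and none lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.00297, and adjusted p = 0.0542 with an estimated correlation). Its median of -0.01 did not share the direction of the test. The other rising lists were MHC class II presentation (0.000569, and adjusted p = 0.256 with an estimated correlation), MHC class I presentation (0.048 and 0.256), B cell (0.00825 and 0.494), macrophage (0.0378 and 0.34) and monocyte markers (0.0268 and 0.103), and the other falling ones ribosomal proteins (0.00018 and 0.504), oxidative phosphorylation (0.032 and 0.596) and chemokines and cytokines (0.043 and 0.378). Without CKO replicate 1 the MHC class I, B cell, macrophage, monocyte and chemokine lists lost their call, without WT replicate 1 the MHC class I, macrophage and monocyte lists, without WT replicate 2 the MHC class I, chemokine and oxidative phosphorylation lists, and without CKO replicate 2 the last of these and the chemokine list. The highest camera adjusted p in these fits was 0.251 for MHC class I, 0.101 for B cell, 0.891 for macrophage, 0.0963 for monocyte, 0.599 for oxidative phosphorylation and 0.47 for chemokine genes. The other 16 lists ranged from 0.0867 to 0.932.

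**Figure D3:**
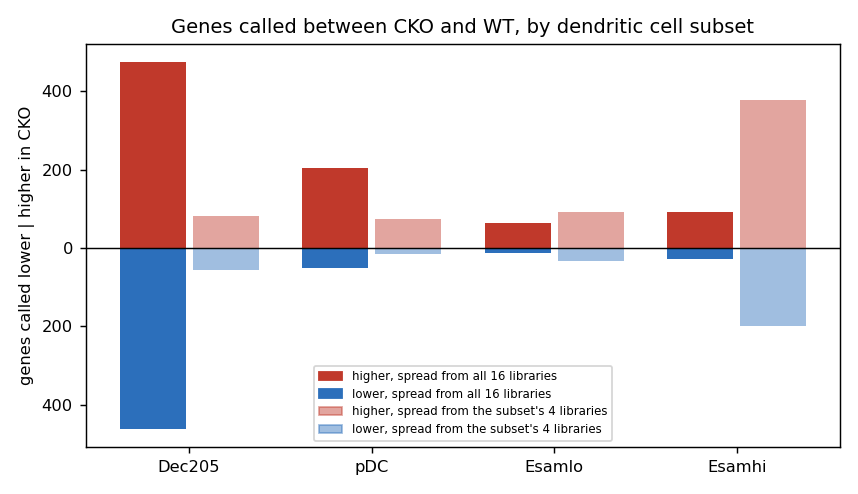
Number of genes called higher (upward, red) and lower (downward, blue) in CKO at an adjusted p under 0.05 in edgeR, for each subset, with the spread shared by all 16 libraries (dark) or taken from the subset's own 4 libraries (light). Dec205 had 935 calls with the shared spread and 136 with its own, and Esamhi had 121 and 578.

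Some changes were shared by the subsets. On the average over the 4 subsets 541 genes were higher and 261 lower, 802 in all, a total that fell or rose with the library left out. In all 4 subsets 11 genes were called higher and 4 lower, the latter being the Y-linked Ddx3y, Kdm5d, Uty and Eif2s3y. Of those called higher, Xist and Kdm6a are X-linked, and Col17a1, Plcb4 and Pros1 are autosomal. Itgax, which encodes CD11c, was singled out after its values were seen, with log2 fold changes of 0.51, 0.70, 0.65 and 0.65 in Dec205, pDC, Esamlo and Esamhi. Calls of Esamlo and Esamhi shared 48 higher genes (45 autosomal) against 0.425 for independent lists, and 7 lower genes, of which 3 were autosomal (Fisher's exact adjusted p = 2.93e-96 and 1.6e-16). Dec205 shared 64 higher genes with pDC against 6.98 for independent lists (Fisher's exact adjusted p = 1.38e-43). The lower calls of pDC and Esamlo shared 4 genes, none of them autosomal. All subsets shared 1 estimate of spread per gene, and same-numbered libraries could share an animal. The lists were thus not independent, and these Fisher p-values can be too small.

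Itgax and its neighbours on chromosome 7, from 128062640 to 128206366 (GRCm38), were looked at after the call of Itgax was seen. On the average over the subsets, all 5 tested genes of this stretch were higher in CKO: Itgam (log2 fold change 1.28, SE 0.15), Itgax (0.63, SE 0.06), Itgad (1.05, SE 0.1), 4931431B13Rik (1.88, SE 0.5) and Cox6a2 (4.13, SE 0.31). Itgam was at 1.35, 2.62, 0.71 and 0.43 in Dec205, pDC, Esamlo and Esamhi (joint adjusted p = 0.0422), and Cox6a2 at 6.34, 1.35, 4.96 and 3.89 (0.0176). In WT, Cox6a2 was at 275 CPM in pDC but at 0.0718, 0.531 and 0.551 CPM in Dec205, Esamlo and Esamhi. Its larger folds thus started from very low levels. Of the 20 tested genes flanking the stretch, whose ends were set by the calls, none was called higher, and their median was 0.06. Itgam counts among the cDC2 and Cox6a2 among the pDC identity genes.

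**Figure D4:**
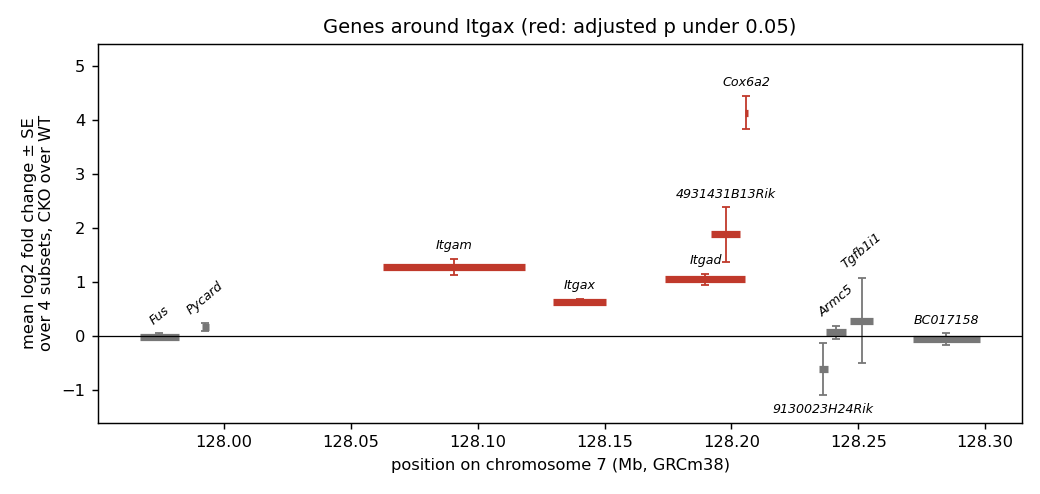
Mean log2 fold change over the 4 subsets (CKO over WT, whiskers SE) of the tested genes around Itgax, by position on chromosome 7 in Mb (GRCm38); bars span each gene and red marks an edgeR adjusted p under 0.05. The 5 genes from Itgam to Cox6a2 were higher in CKO, and no gene drawn on either side was called.

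Other changes differed between subsets by a test of the difference itself. The joint test called 337 genes, and the effect in Dec205 differed from that in pDC for 333 genes, in Esamlo for 211 and in Esamhi for 263. Without Dec205 WT replicate 1 these counts were 532, 674, 466 and 517, and without Dec205 CKO replicate 2 those against pDC and Esamlo were 532 and 350. The count against pDC was 198 without pDC CKO replicate 2, and that against Esamlo 79 to 138 without 1 Esamlo library and 140 without Esamhi CKO replicate 1. The count against Esamhi was 113 to 122 without 1 Esamhi library, and the joint count 220 without Esamhi WT replicate 1 and 219 without Esamhi CKO replicate 2. All these tests shared 1 spread per gene over the libraries, though Dec205 replicates lay furthest apart. In limma-voom, Dec205 against pDC, Esamlo and Esamhi gave 219, 186 and 274 calls. With 1 quality weight per group there, it gave 57, 73 and 170. Cdh1 had log2 fold changes of 2.06 in Dec205, -0.12 in pDC, 7.20 in Esamlo and 10.91 in Esamhi (joint adjusted p = 2.45e-05). Plcb4 was at 0.85, 2.48, 4.24 and 4.03 in the same order (6.39e-05). Slc12a7 was at -0.36, 0.13, 3.09 and 4.80 (0.000336). Plac8 was at 2.61, 0.13, 0.78 and 1.01 and Cxx1b at 2.92, 0.26, 0.28 and 0.03 (0.000142 for each), Fam217b at 5.47, 0.60, 2.28 and 2.82 (0.000215). Rasgef1b (2.07) and Stmn1 (1.64), a microtubule regulator, stood out in pDC, with joint adjusted p of 0.000142 and 0.000176. Clec2i went from -1.20 in Dec205 to 0.78, 1.17 and 0.71 in the others (0.000328), and Ms4a6c was at 1.77 and 1.21 in Dec205 and pDC and at -0.19 and 0.08 in Esamlo and Esamhi (0.000402). Among lists, the interferon genes rose more in Dec205 than in pDC, Esamlo and Esamhi (camera adjusted p of the difference 6.56e-06, 4.15e-09 and 4.62e-14), and with an estimated correlation the adjusted p was 0.207, 0.115 and 0.0933. The maturation genes fell more in Dec205 than in these subsets (0.000604, 1.43e-07 and 3.97e-09, and adjusted p = 0.251, 0.117 and 0.224 with an estimated correlation).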

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

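The tests of sex, of the ratio of calls with each subset's own spread, of false calls with each gene's own dispersion and of the genes flanking Itgax were chosen after the result was seen. The tests of the differences between subsets and the splits of the libraries were planned.

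A test of the difference itself found that the effect of genotype differed between the subsets for 337 genes (edgeR quasi-likelihood joint test, adjusted p under 0.05), a count that was 532 without Dec205 WT replicate 1, 220 without Esamhi WT replicate 1 and 219 without Esamhi CKO replicate 2. The test shared 1 spread per gene over all libraries, though Dec205 replicates lay furthest apart. For Dec205 against pDC, Esamlo and Esamhi, limma-voom called 219, 186 and 274 genes, and 57, 73 and 170 with 1 quality weight per group. The 10 of the 337 genes that the naming rule takes were Cdh1 (adjusted p = 2.45e-05), Plcb4 (6.39e-05), Rasgef1b, Cxx1b and Plac8 (0.000142 each), Stmn1 (0.000176), Fam217b (0.000215), Clec2i (0.000328), Slc12a7 (0.000336) and Ms4a6c (0.000402). Among gene lists, Dec205 differed from pDC in pDC identity (camera adjusted p = 0.000657), interferon response (6.56e-06), maturation (0.000604), Toll-like receptor (0.0418), cell cycle (2.34e-10), B cell (0.0252), monocyte (0.000172) and sex-linked genes (0.0453). It differed from Esamlo in pDC identity (0.00998), interferon response (4.15e-09), maturation (1.43e-07), cell cycle (0.000751), monocyte (0.0105), ribosomal protein (1.11e-05), ESAM-low and monocyte-like (0.00124), C-type lectin (0.00896) and oxidative phosphorylation genes (0.0232). It differed from Esamhi in interferon response (4.62e-14), maturation (3.97e-09), cell cycle (3.09e-07), ribosomal protein (0.000272), B cell and plasma cell (0.0367 each) and neutrophil genes (0.0486). None of these list differences held with an estimated correlation, where the lowest adjusted p was 0.0548, for monocyte genes against pDC.

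Genotype and sex-linked transcripts went together. All 16 libraries followed genotype, with 4 Y-linked genes above 5 CPM and Xist below it in WT and the reverse in CKO. By these transcripts the WT libraries were male and the CKO libraries female, though the labels give no sex. Of 100 splits of the libraries within subsets, drawn from 648 distinct ones, only the real one (1 of 100) gave as many calls. It gave 802 on the average over the subsets, against a median of 1 in the others. The highest other gave 314, but it still parted all 4 subsets by genotype, with the direction reversed in some. The excess of the real split argues against scatter between independent libraries. Chance differences between a few animals stay open, since libraries of a group or of the same number may share an animal. For the autosomal calls sex cannot be told apart from genotype, because no group of libraries held both genotypes in 1 sex; the odds ratio of X-linked genes among the calls was 1.2. The deletion of Etv6 stays open beside it for each autosomal gene.

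Dec205 had 935 calls and Esamhi 121, under a spread shared by all libraries. With each subset's own spread the ratio of calls was 0.235, so unequal replicate spread could account for the order of the counts. In 8 simulations of unchanged genes with each group's own dispersion Dec205 had 12.2 calls on average. This was under the bound written beforehand for excluding false calls. With each gene's dispersion from its subset's own 4 libraries, which overstates the extremes, Dec205 had 169 (133 to 193), over that bound. No gene was changed in these simulations, so the adjusted p set a stricter cutoff there than in the real data. Neither value therefore counts the false calls among the 935. The variance of the log2 change that replicates share was 2.41 times as large in Dec205 as in Esamhi (0.236 against 0.0981 over 8653 autosomal genes), as a larger change of expression in Dec205 would give. The number of false calls, unequal spread and a larger change thus all stay open, and the counts of calls do not rank the subsets.

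On the average over the subsets the genes from Itgam to Cox6a2 were higher together, but unevenly between subsets for Itgam and Cox6a2 (joint edgeR adjusted p = 0.0422 and 0.0176). Both genes differed widely in WT level between the subsets, so this unevenness does not bear on the number of copies. With the real order counted beside 1000 shuffles of the calls, the share with a run of 5 neighbours called higher was 0.003. This argues against scatter of independent calls but not against neighbours regulated together, since the data also held a run of 6 Oas genes on chromosome 5. However, 4931431B13Rik lies within Itgad, and Cox6a2 overlaps the end of Itgad. Shared reads could thus lengthen the run and make the share too small. None of the 20 flanking genes was called higher (0 genes), but the ends of the block were set by which neighbours were called, so this value decides little. Extra copies of this block from a transgene and shared regulation of its genes both may account for it and cannot be told apart here, since the labels name no Cre driver and no biological explanation was tested. Calls of Itgam, Itgax, Itgad and Cox6a2 therefore may or may not concern Etv6.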

How the results depend on the processing

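The fits with 1 quality weight per group and on autosomal genes were chosen after the data were seen; the others were planned. RLE, upper quartile and library size scaling, both other low-count filters, edgeR without robust estimation and autosomal genes only left each count of calls within 1.5 times its value. The tool, the size of fold asked for and the libraries that set the spread moved the counts; the cause was not tested where not stated. Of the results for single named genes and lists under the alternatives, 3998 stayed on their side of the threshold, 828 lost it and 0 reversed. These results were taken because they were called in the main fit, and most alternatives refit the same counts, so reversals were unlikely from the start. Among the signatures in their own subset and Etv6, which were taken whether called or not, 5 results reversed. The joint test has no glmTreat form and was not run with it. Depth sets a floor of 3 counts, 0.143 to 0.228 CPM.

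With glmTreat against a fold of 1.5, a stricter question by construction, calls were 257 in Dec205, 114 in pDC, 20 in Esamlo, 33 in Esamhi, 107 on average, and 125, 76 and 85 for the difference of Dec205 from pDC, Esamlo and Esamhi. DESeq2 gave 1707, 549, 250, 305 and 1347 in that order, 869, 593 and 643 for the differences, 1082 in the joint test (337 with edgeR) and 327 genes called the same way in at least 2 subsets (151 with edgeR). With only the 4 libraries of a subset calls were 136, 91, 126 and 578. Voom with group weights gave 325, 158, 313 and 636 in the subsets, 57, 73 and 170 for the differences and 190 jointly. Plain limma-voom gave 133 in Esamlo, 208 in Esamhi and 219 for Dec205 against pDC.

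The labels do not say that replicate numbers pair samples, and deviations of same-numbered WT and CKO libraries of a subset correlated at -0.0692 to 0.0169. The 12 pairs of subsets within a genotype were all positive but weak (0.00719 to 0.116), and of all 28 pairs of groups 2 were over 0.1. The numbers were not used as pairs, but same-numbered libraries of a genotype could come from the same animal. The average over the subsets would then count libraries of the same animal as independent, and its p-values would be too small. With the replicate block, calls were 971 in Dec205, 260 in pDC, 86 in Esamlo, 136 in Esamhi and 831 on average; as a block by genotype 945, 275, 104, 135 and 841. With a block by subset, calls were 169 in pDC, 48 in Esamlo, 66 in Esamhi, 201, 88 and 139 for the differences and 184 jointly.

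Leaving out 1 library (the lone library left is assumed to vary like the other groups) gave 585 (without WT replicate 2) to 1328 calls in Dec205, 28 to 38 in Esamlo, 44 to 48 in Esamhi and 520 (without Esamlo CKO replicate 1) to 1101 on average. It gave 198 (without pDC CKO replicate 2) to 674 (without Dec205 WT replicate 1) for Dec205 against pDC, 79 to 466 against Esamlo, 113 to 517 against Esamhi and 219 to 532 jointly; the second highest against pDC was 532, without Dec205 CKO replicate 2. In the same fits pDC had 176 to 281 calls.

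Lists called, the sex-linked one included, numbered 6 in Dec205, 5 in pDC, 13 in Esamlo and 14 in Esamhi. With an estimated correlation they were 2, 2, 3 and 4, and with fry, which asks another question, 8, 8 and 9 in pDC, Esamlo and Esamhi. Without 1 library they were 4 to 8 in pDC (8 without CKO replicate 1) and 7 (without WT replicate 1) to 16 in Esamlo. The median of the Dec205 signature in Dec205 was -0.13 with a minimum of 2 on the log2 scale, where it did not pass camera even without adjustment, and -0.28 to -0.13 without 1 library. With signatures chosen from WT libraries, a choice that favours falls, medians were -0.05 in pDC, -0.12 in Esamlo and -0.06 in Esamhi, each past camera without adjustment; without 1 library the Esamlo median was -0.17 to 0.07. The Esamhi median, 0 at first, was -0.13 with a minimum of 2 and -0.07 (without WT replicate 2) to 0.03 without 1 library, also negative (-0.06) without CKO replicate 2. Etv6 in pDC, at -0.03 and not called, was -0.12 to 0.06 without 1 library.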

Other observations

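The test of calls around Etv6 was chosen after the result was seen, and the others were planned.

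On the average over the 4 subsets, the type I interferon list had 15 of 36 genes higher and none lower (20 and 2 adjusted over the list alone, median log2 fold change 0.28, camera adjusted p = 1.76e-14, and adjusted p = 0.0431 with an estimated correlation). The B cell list had 8 of 15 genes higher and none lower (10 and 0 adjusted over the list alone, median 0.81, camera adjusted p = 1.49e-07, and adjusted p = 0.23 with an estimated correlation). Its mean log2 CPM was higher in CKO replicate 1 than in CKO replicate 2 in every subset (5.09 and 4.20 in Dec205, 4.83 and 4.27 in pDC, 5.76 and 4.79 in Esamlo, 4.63 and 4.37 in Esamhi). Without CKO replicate 1 its camera call was lost in Esamlo and Esamhi. Apoptosis regulators had 5 of 18 genes higher and none lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.00354, and adjusted p = 0.0537 with an estimated correlation). Monocyte markers (camera adjusted p = 0.00709, and adjusted p = 0.0654 with an estimated correlation) and DC transcription factors and growth factor receptors (0.0287 and 0.132) were also higher.

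Signatures of other subsets moved in part with camera, and their calls depended on the setting. Under the alternatives camera was read without adjustment. The Esamhi signature of 86 genes had 6 higher and 12 lower in Dec205 (median -0.26, camera adjusted p = 0.021, and adjusted p = 0.198 with an estimated correlation). Its median ranged from -0.33 to 0 over 10 alternatives, among them -0.03 without WT replicate 1 and -0.14 without WT replicate 2, and in 2 of the 10, both with the signature chosen in another way, it did not pass. In Esamlo it had 1 higher and 0 lower (median 0.15, camera adjusted p = 0.0379, and adjusted p = 0.198 with an estimated correlation). There the median ranged from 0.05, without CKO replicate 2, to 0.64, and 4 of the 10 alternatives did not pass, among them those without CKO replicate 2 and without WT replicate 2. The pDC signature in Esamlo had 12 higher and 5 lower (median 0.11, with the same 2 adjusted p-values), and without CKO replicate 1 its median was 0 and did not pass.

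Within 10 Mb of Etv6 on chromosome 6, 9 of 142 tested genes were called on the average over the subsets, against 8.27 for calls spread evenly (Fisher's exact p = 0.719). Bcl2l14, 4.18-fold higher in pDC, starts at 134396329, close to the end of Etv6 at 134270158. Tspan9, named in Dec205, and Cd4 and Lag3, named in Esamhi, also start within this window. The count covers the average only, so a local effect on these genes in their subsets was not tested.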
